A study of Mus musculus and Homo sapiens with 43 samples.

How the data were processed

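RNA-seq values of 24 libraries were analysed: WT and Pcgf2 KO cells as ESC, EB day 3, EB day 8 and NPC, and Phc1 KO and Phc1-SAM KO cells as ESC and NPC, with 2 libraries per group. The authors deposited 2 tables of TPM (the share of each gene in the transcripts of a library), made with kallisto on mm10. Their labels also name DESeq2, STAR, SAMtools, BWA, deepTools and MACS2 for the study, without saying which step each served. Versions, the annotation release and the step from transcripts to genes are not given in the sources used here. The deposited TPM of the first table and of the knock-out columns of the second were sums over the transcripts of each gene, with column totals of 0.9972 to 1.005 and 0.9759 to 0.9802 of the nominal TPM total. TPM keep no read counts, so depth is unknown and no interval from counting error could be given.

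The 4 WT columns of the second table appeared to have another unit than the plan had assumed. Judged from the values alone, their deposited TPM appeared to come from a single transcript per gene, which the labels do not state: they summed to 0.3811 to 0.5028 of that total, 0.223% to 0.268% of their values above 0 had more than 6 digits against 50.3% to 53.5% in the first table, and 26.4% to 28.1% of genes at 5 TPM or more in the first table were listed at 0. The difference between WT replicates had a rank correlation across genes of 0.47 in ESC and 0.49 in NPC between the tables, as columns from the same samples would. For comparisons of Phc1 KO and Phc1-SAM KO with WT, each WT column was divided by a factor (0.63, 0.661, 0.479 and 0.498) that matched it to the first table, and tests were limited to genes whose WT values agreed within 1.5-fold between the tables (22189 of 31268 genes in ESC and 21094 in NPC, before the filter on low values). Genes near 0 in WT in both tables met that limit readily, and such genes can rise but hardly fall. Of 15 anterior Hox genes, 12 were tested in ESC and 2 in NPC. Phc1 KO and Phc1-SAM KO were compared with each other without the WT columns. These steps were chosen after seeing the data.

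Comparisons, gene lists, tests, filters and most alternatives were chosen before the data were examined. Values were taken as log2(TPM + 1). Genes with at least 1 TPM in at least 2 libraries of the fit were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), two-sided, with one mean per group and the spread shared by all libraries of a table. P values were adjusted by Benjamini-Hochberg within each comparison, at 0.05. The labels do not say whether replicates were separate cultures or lines, so p values measure the spread between libraries. Tests were run only within a table, and 18 comparisons and summaries were planned. Differences of the Pcgf2 KO effect between stages were tested as contrasts of the same fit.

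The 26 gene lists were tested with camera at an inter-gene correlation of 0.01, with adjustment over all lists and comparisons, and again with the correlation estimated from the data and with fry, which asks whether the genes of a list move one way without comparing them with other genes. Of 158 camera calls, 0 passed with an estimated correlation, where the smallest adjusted p was 0.053, and fry called 332. With 2 libraries per group an estimated correlation carries large uncertainty. Calls also ended where the estimate lay below 0.01, so its size does not account for every loss. For naive genes in Phc1 KO NPC against WT it was -0.013, with camera adjusted p of 1.6e-09 at the fixed and 0.053 at the estimated correlation. The lists were PRC1 subunits, PRC2 subunits, CTCF and cohesin, naive pluripotency, primed epiblast, neural progenitor, neuron, anterior Hox, posterior Hox, retinoic acid response, Polycomb-target transcription factors, Irx3 locus, primitive streak and mesoderm, endoderm, trophectoderm, cardiac and muscle, blood and endothelium, fibroblast, neural crest, forebrain, germline, 2-cell-like, Cdk inhibitors, p53 targets, ribosomal proteins and mitochondrial genome.

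Named genes followed a rule of 3 parts. The first part was Pcgf2, Bmi1 (Pcgf4), Phc1, Irx3, Irx5, Irx6 and Fto in every library. The second was, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 TPM in one group and no overlap between the libraries of the groups. The third was, per list, up to 4 called members with the largest change, or the 2 most abundant where none was called. Predicted genes without a symbol were counted but not named. Gene symbols were matched to the GRCm38 annotation for 34286 of 35245 genes in the first table and 32163 of 32231 in the second, and positions come from it.

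Genes induced in WT NPC were picked with one WT NPC library (at least 4-fold above the WT ESC mean) and compared in the other, both ways round. Overlaps of calls between knock-outs were set against independent lists and 20 simulated draws of unchanged knock-outs sharing the same controls. The fit was tested on simulated data: of genes changed by a log2 of 1, it called 92% to 98% in the first table and 84% to 90% for Phc1 KO against WT in ESC, with 3.54% to 6.64% false calls. Changed genes were drawn only from genes of higher mean level, with the spread taken from the fit. Recovery of genes at low TPM, such as Irx5 or Hoxd13 in ESC, was thus not tested. Alternatives were a pseudocount of 0.1, no filter, a limit of 5 TPM, median-of-ratios scaling, quantile normalization, only the groups compared, the replicate number as a block, leaving out each library, a 2-fold limit, and, chosen after seeing the data, the WT columns as deposited, agreement within 1.2-fold, a fit without the EB day 8 libraries and one without the ESC Phc1 KO libraries. ChIP-seq and Hi-C samples and Pcgf4 KO and Irx3-anchor KO cells were not analysed here, and Pcgf2 KO was not tested against Phc1 KO because they sit in different tables. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.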

Results

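Messenger RNA was measured by RNA-seq in 24 libraries of mouse E14 embryonic stem cells (ESC) and their differentiated progeny, which fell into 12 groups of 2 libraries. ESC were grown with LIF and the inhibitors PD0325901 (1 µM) and CHIR99021 (3 µM), a medium that holds cells in naive pluripotency. Embryoid bodies (EB), which are aggregates that differentiate spontaneously, were sampled on day 3 and day 8, and neural progenitor cells (NPC) came from aggregates given 5 µM retinoic acid from day 4 to day 8. A first deposited table held wild type (WT) and Pcgf2 KO cells at all 4 stages, 16 libraries in total. A second table held Phc1 KO and Phc1-SAM KO cells as ESC and NPC, 8 libraries, beside 4 WT columns from the same ESC and NPC samples as the first table. Pcgf2 and Phc1 encode subunits of canonical Polycomb repressive complex 1 (PRC1), which keeps developmental genes silent, and the SAM domain of Phc1 lets the complex polymerise. Values were TPM, the share of each gene in the transcripts of a library. They keep no record of sequencing depth, so the depth of each library is unknown. The 16 libraries of the first table listed 35245 genes and had 13131 to 15374 genes at 1 TPM or more. The 8 knock-out libraries of the second table listed 32231 genes and had 13469 to 14550. Replicates correlated across genes with r of 0.993 to 0.995 in the first table and 0.992 to 0.995 among the knock-out libraries of the second. Values are given as mean ± SD with n = 2 libraries per group throughout.

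The genes that were edited or that the study centres on were examined first in every group. Pcgf2 (chromosome 11, 97688821 to 97702434 in GRCm38) was transcribed at 232 ± 74 TPM in the ESC libraries labelled Pcgf2 KO and at 152 ± 3.9 TPM in WT ESC, and the 2 knock-out libraries differed from each other (180 and 284 TPM). In EB its transcript was more abundant in the libraries labelled Pcgf2 KO, at 172 ± 4.5 against 107 ± 6.3 TPM on day 3 (log2 fold change 0.69, adjusted p = 0.0043) and 182 ± 23 against 73.6 ± 1.7 TPM on day 8 (log2 fold change 1.29, adjusted p = 9.1e-05). Pcgf2 in NPC stood at 151 ± 10 TPM in the knock-out and 120 ± 4.5 TPM in WT (log2 fold change 0.33, adjusted p = 0.094). The call in ESC (log2 fold change 0.57, adjusted p = 0.017) ended when WT replicate 1 (adjusted p = 0.053), WT replicate 2 (adjusted p = 0.084) or knock-out replicate 2 (adjusted p = 0.12) was left out, and when only the groups compared entered the fit (adjusted p = 0.11). The NPC difference passed with median-of-ratios scaling (adjusted p = 0.018) and with only the groups compared (adjusted p = 0.0087). Phc1 (chromosome 6, 122317731 to 122340227) reached 151 ± 0.88 TPM in ESC labelled Phc1 KO against 256 ± 14 TPM in ESC labelled Phc1-SAM KO (log2 fold change -0.76, adjusted p = 5.4e-05), while in NPC it stood at 108 ± 2 and 107 ± 5.7 TPM. Pou5f1 and Nanog were lower in ESC labelled Phc1 KO as well, so a lower level there was not particular to the edited gene. Phc1 in WT ESC of the first table was at 217 ± 22 TPM, a level set here across tables without a test. No edited gene was thus silent in the libraries named after it. A sum of TPM per gene cannot show a small deletion or the loss of a domain, so the genotypes below are those of the labels. The WT and Pcgf2 KO cells also differed in transcripts of the Y chromosome at 3 of the 4 stages: Eif2s3y, chosen after its values were seen, stood at 0.435 ± 0.018 against 56.1 ± 13 TPM in ESC, 2.12 ± 0.93 against 48.2 ± 3.5 TPM on EB day 3 and 1.58 ± 0.22 against 52.8 ± 5.5 TPM in NPC. On EB day 8 it stood at 57.5 ± 10 TPM in WT and 70.9 ± 7.3 TPM in Pcgf2 KO.

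**Figure D1:**
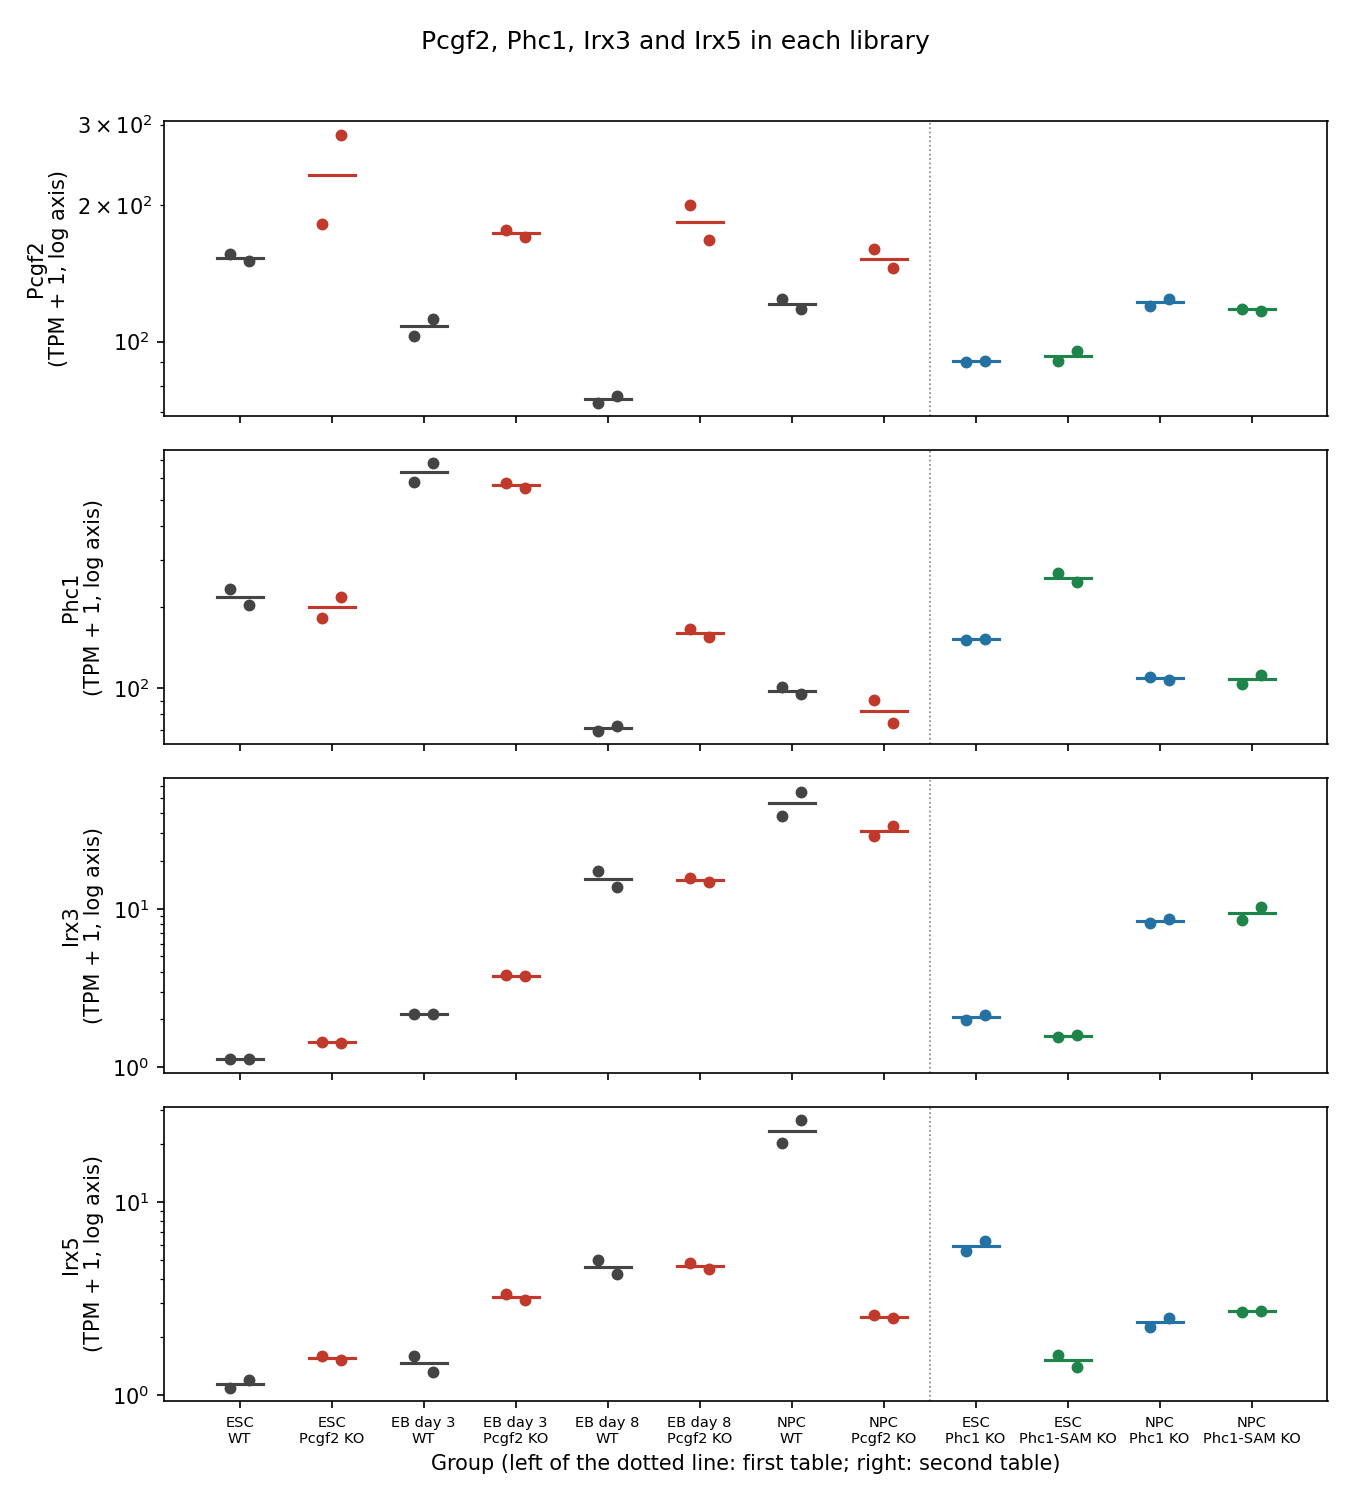
TPM + 1 of Pcgf2, Phc1, Irx3 and Irx5 on a log axis, with a point per library and a line at the mean of each group. Groups on either side of the dotted line come from different tables and were not tested against each other.

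The comparison of WT stages asked how far the cells had left pluripotency and what they had become. On EB day 3 the naive factors fell, with Klf4 at 1.32 ± 0.13 TPM against 100 ± 2.5 TPM in ESC (log2 fold change -5.44). Tbx3, a factor that sustains self-renewal, fell to 0.894 ± 0.19 from 93.2 ± 2.9 TPM (log2 fold change -5.64). Fgf5, which marks the post-implantation epiblast, rose from 0.229 ± 0.049 to 112 ± 2.3 TPM (log2 fold change 6.53, adjusted p = 2.3e-10). Phc1 itself rose to 630 ± 72 TPM (log2 fold change 1.53). Of the naive pluripotency list, 16 of 19 genes fell, and of the primed epiblast list 11 of 14 rose (camera adjusted p = 4.3e-15 and 0.00017; adjusted p = 0.053 and 0.28 with an estimated correlation). The p53 target list had 13 of 15 genes up, among them Pmaip1, which promotes cell death, at 35.8 ± 1 against 3.74 ± 0.44 TPM (adjusted p = 3.1e-05, and 0.16 with an estimated correlation). Counts adjusted over the list alone were the same for these 3 lists. In all, 10003 of 17938 genes were called, 6572 up and 3431 down, with a median shift over all genes of 0.15. That split depended on scaling: median-of-ratios scaling gave 4762 up and 5384 down, and quantile normalization 5165 up and 4761 down.

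By EB day 8 the WT aggregates carried transcripts of several germ layers. WT ESC and WT EB day 8 also differed in Y-linked transcripts, with Eif2s3y at 0.008 and 0.811 of its Pcgf2 KO level. Differences between them can thus not be assigned to differentiation alone. Apob, a lipoprotein gene of visceral endoderm, rose from 0.192 ± 0.0081 to 191 ± 18 TPM (log2 fold change 7.33). Hand1, a factor of extraembryonic and lateral mesoderm, rose from 0.323 ± 0.21 to 575 ± 20 TPM (log2 fold change 8.77). Postn, a matrix gene of fibroblasts, rose from 0.00882 ± 0.012 to 406 ± 31 TPM (log2 fold change 8.66). The imprinted growth factor gene Igf2 reached 3300 ± 14 TPM. All 23 endoderm genes tested rose (adjusted p = 2e-10, and 0.058 with an estimated correlation), as did 11 of 12 blood and endothelium genes and 11 of 12 fibroblast genes (adjusted p = 9.7e-05 and 9.5e-05; 0.13 and 0.084 with an estimated correlation). Adjusted over the list alone, these counts were the same. Limma called 12309 genes, 8105 up and 4204 down, with a median shift of 0.25. Median-of-ratios scaling gave 6232 up and 6325 down, and quantile normalization 5771 up and 6497 down.

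WT NPC gained neural and Hox transcripts beside transcripts of other lineages. Pou5f1, the core pluripotency factor, dropped from 1550 ± 92 TPM in ESC to 1.14 ± 0.48 TPM (log2 fold change -9.51, adjusted p = 9.5e-13), and Nanog from 452 ± 12 to 2.02 ± 0.12 TPM (log2 fold change -7.23). Pax6, a neural progenitor factor, rose from 0.438 ± 0.37 to 63.2 ± 15 TPM (log2 fold change 5.48). Hes5, a Notch target of dividing progenitors, rose from 0.0589 ± 0.03 to 73.6 ± 26 TPM (log2 fold change 6.09). Genes that respond to retinoic acid were high, with Cyp26b1, which degrades the ligand, at 471 ± 1.9 against 0.125 ± 0.056 TPM (log2 fold change 8.71). Hoxa5 was at 290 ± 8.1 against 0.437 ± 0.07 TPM (log2 fold change 7.66). All 15 anterior Hox genes, 18 of 19 retinoic acid response genes and 25 of 27 neural progenitor genes rose (adjusted p = 1.3e-06, 1.6e-05 and 3.2e-05; 0.068, 0.053 and 0.35 with an estimated correlation). All 19 naive genes fell (adjusted p = 1.2e-16, and 0.053 with an estimated correlation), and 42 of 50 transcription factors of the Polycomb-target list rose (adjusted p = 3.2e-05, and 0.13 with an estimated correlation). Blood and endothelium genes had 11 of 12 up and endoderm genes 20 of 23 (adjusted p = 0.0045 and 0.0026; 0.21 and 0.28 with an estimated correlation), and fibroblast genes had 8 of 12 up without passing (adjusted p = 0.12). The embryonic globin gene Hbb-y, which resembles other globin genes, was at 249 ± 13 against 0.0452 ± 0.064 TPM. Adjusted over the list alone, all these counts were the same. Called genes numbered 13447, 9579 up and 3868 down, with a median shift of 0.46, whereas median-of-ratios scaling gave 6442 up and 6620 down and quantile normalization 6376 up and 6432 down.

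NPC differed from EB day 8 in the retinoic acid that the culture labels name, and WT cells with and without it were compared. These WT groups also differed in Y-linked transcripts, with Eif2s3y at 0.03 of Pcgf2 KO in NPC and 0.811 on EB day 8. Differences between them can thus not be assigned to the ligand alone. Hoxa5 (290 ± 8.1 against 0.94 ± 0.46 TPM; log2 fold change 7.25) and the nuclear receptor gene Nr2f1 (222 ± 21 against 1.24 ± 0.76 TPM; log2 fold change 6.68) were higher in NPC. Neurog1, a proneural factor, was listed at 0 on EB day 8 and stood at 63.4 ± 22 TPM in NPC. Apob (0.806 ± 0.43 against 191 ± 18 TPM; log2 fold change -6.75), Hand1 (log2 fold change -7.93) and Postn (log2 fold change -6.64) were lower. The neuron list had 25 of 26 genes up and the endoderm list 21 of 23 down (adjusted p = 2e-10 and 4.6e-14; 0.15 and 0.053 with an estimated correlation), and 8 of 11 trophectoderm genes fell (adjusted p = 9.5e-05, and 0.053 with an estimated correlation). These counts did not change when adjusted over the list alone, except that 2 trophectoderm genes in place of 1 then rose. The fit called 10444 genes, 6831 up and 3613 down, with a median shift of 0.16 (4683 and 5118 with median-of-ratios scaling, 5273 and 4791 with quantile normalization).

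In ESC, Pcgf2 KO was compared with WT to find genes kept low by Pcgf2 before differentiation. Posterior Hox genes, classical Polycomb targets, left their floor: Hoxd13 stood at 7.12 ± 0.081 against 0.677 ± 0.094 TPM (log2 fold change 2.28, adjusted p = 1.5e-06). Hoxa9 was at 4.72 ± 0.061 against 0.207 ± 0.017 TPM (log2 fold change 2.25). Zscan4f, a marker of the rare 2-cell-like state, rose from 5.14 ± 1 to 73.4 ± 18 TPM (log2 fold change 3.59), though Zscan4 copies share reads and the gene cannot be told from its relatives. Among p53 targets, the cell cycle gene Ccng1 rose from 50.8 ± 1.3 to 236 ± 7.7 TPM (log2 fold change 2.19). The stress gene Trp53inp1 rose from 26.8 ± 3.4 to 134 ± 16 TPM (log2 fold change 2.28). The PRC2 subunit gene Suz12 rose too, at 187 ± 33 against 69.3 ± 5.8 TPM (log2 fold change 1.41). Lefty1, a Nodal antagonist made by naive cells, dropped from 125 ± 7.7 to 4.12 ± 0.1 TPM (log2 fold change -4.62, adjusted p = 2.1e-09), and Lefty2 from 134 ± 2.6 to 18.1 ± 1.3 TPM (log2 fold change -2.82). The methyltransferase gene Dnmt3a fell from 72.5 ± 3.5 to 22.4 ± 1.4 TPM (log2 fold change -1.65), and Cdkn1c, a cell cycle inhibitor gene (17.1 ± 0.45 to 1.76 ± 0.69 TPM), and Phlda2, a placental growth gene (97.9 ± 7.3 to 11 ± 1.5 TPM) fell as well.

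The posterior Hox list had 20 of 23 genes up in Pcgf2 KO ESC (adjusted p = 8e-09, and 0.084 with an estimated correlation), the 2-cell-like list 11 of 11 (adjusted p = 2.9e-09, and 0.11) and the p53 list 13 of 15 (adjusted p = 1.4e-08, and 0.091). Anterior Hox genes had 6 of 15 up, and 7 adjusted over the list alone (adjusted p = 0.033, and 0.31 with an estimated correlation; 0.05 with a limit of 5 TPM), led by Hoxd4 at 2.98 ± 0.67 against 0.21 ± 0.056 TPM. Adjusted over the list alone, the first 3 counts were the same. Of PRC1 subunit genes, 14 of 29 rose and 1 fell, and of Polycomb-target factors 19 of 50 rose and 2 fell, without passing the list test (adjusted p = 0.097 and 0.056), with 15 and 20 rises adjusted over the list alone. Nefm, a neurofilament gene, rose from 0.278 ± 0.081 to 11.2 ± 1 TPM although the neuron list as a whole had 5 genes up and 6 down, 7 down adjusted over the list alone (adjusted p = 0.098). Of 17938 genes, 6452 were called, 4473 up and 1979 down, and 1209 of these moved at least 2-fold, 1007 up and 202 down. With only the groups compared in the fit the count was 4098. The excess of rises depended on scaling, since median-of-ratios scaling gave 3422 up and 3675 down and quantile normalization 3027 up and 3259 down, while the Hox, 2-cell-like and p53 lists rose under each.

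On EB day 3 the question was whether Pcgf2 KO cells left the naive state on time. Klf2, a naive factor, remained at 94 ± 9.1 TPM against 6.96 ± 0.54 TPM in WT (log2 fold change 3.58, adjusted p = 1.9e-09). Fbxo15 was at 58.2 ± 1.4 against 3.51 ± 0.26 TPM (log2 fold change 3.72) and Zfp42, which encodes Rex1, was at 244 ± 0.92 against 26.8 ± 0.79 TPM (log2 fold change 3.14). Of primitive streak and mesoderm genes, 7 of 23 were up and 5 down, also adjusted over the list alone (median 0.05, adjusted p = 0.39), and with quantile normalization 5 were up and 6 down (median -0.07). Among those that fell, T (Brachyury) was at 2.27 ± 0.42 against 21.2 ± 10 TPM (log2 fold change -2.69). Fgf8 was at 16.2 ± 2.9 against 40.6 ± 3.3 TPM (log2 fold change -1.28). Dnmt3b, a methyltransferase of the primed epiblast, was at 412 ± 3.6 against 867 ± 40 TPM (log2 fold change -1.07). Of 14 primed epiblast genes, 3 were up and 6 down, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.79). Fgf5 stood at 116 ± 3.5 against 112 ± 2.3 TPM and Otx2 at 168 ± 5.3 against 137 ± 18 TPM. Grb10, an imprinted gene for a growth inhibitor, fell from 103 ± 5.3 to 6.74 ± 1.1 TPM (log2 fold change -3.76). The cohesin gene Stag2 fell from 88.5 ± 0.73 to 40.7 ± 4.2 TPM (log2 fold change -1.11). The germline gene Hormad1 rose from 0.234 ± 0.14 to 9 ± 0.52 TPM (log2 fold change 3.02).

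Of naive genes, 16 of 19 were higher in Pcgf2 KO EB day 3 (adjusted p = 2.3e-13, and 0.053 with an estimated correlation), and 2 others fell when adjusted over the list alone. Posterior Hox had 16 of 23 up (17 adjusted over the list alone) and anterior Hox 10 of 15 (adjusted p = 4.1e-08 and 0.00033; 0.094 and 0.13 with an estimated correlation). Polycomb-target factors had 18 of 50 up and 2 down (adjusted p = 2.9e-05, and 0.13 with an estimated correlation). The germline list had 9 of 17 up and 1 down, and 10 of 13 genes of the mitochondrial genome rose, 11 adjusted over the list alone (adjusted p = 0.00014 and 2.3e-05; 0.11 and 0.41 with an estimated correlation). The mitochondrial call ended with quantile normalization (adjusted p = 0.084). Counts without a separate value were the same when adjusted over the list alone. CTCF and cohesin genes had 2 of 12 up and 8 down, 9 down adjusted over the list alone (adjusted p = 0.16). Called genes came to 8714, 2989 up and 5725 down, with a median shift of -0.11, and median-of-ratios scaling gave 3986 up and 4321 down.

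Day 8 EB addressed whether Pcgf2 KO aggregates formed the lineages seen in WT. Afp, the alpha-fetoprotein gene of yolk sac endoderm, stood at 5.69 ± 0.062 against 56.8 ± 4.7 TPM (log2 fold change -3.11, adjusted p = 6e-08). Apob was at 27.6 ± 2.5 against 191 ± 18 TPM (log2 fold change -2.74) and Postn at 5.63 ± 0.45 against 406 ± 31 TPM (log2 fold change -5.94). Embryonic globin transcripts were lower, Hbb-bh1 at 157 ± 18 against 3580 ± 420 TPM (log2 fold change -4.50), with the limit that globin genes resemble each other in sequence. The growth factor gene Igf2 fell from 3300 ± 14 to 143 ± 8.4 TPM (log2 fold change -4.52) and the Notch ligand gene Dlk1 from 167 ± 9.4 to 5.69 ± 0.73 TPM (log2 fold change -4.65). The cell cycle inhibitor gene Cdkn1c fell from 301 ± 16 to 9.33 ± 1.4 TPM (log2 fold change -4.88) and Grb10 from 153 ± 13 to 8.73 ± 1.9 TPM (log2 fold change -4.00). Epiblast factors were higher than in WT, with Otx2 at 60.4 ± 3.2 against 6.92 ± 0.11 TPM (log2 fold change 2.95). The Nodal co-receptor gene Tdgf1 was at 154 ± 16 against 21.7 ± 1.2 TPM (log2 fold change 2.77). Sox2 stood at 87.3 ± 5.7 against 15.6 ± 2.5 TPM (log2 fold change 2.41) and Hoxc13 at 7.42 ± 0.095 against 1.16 ± 0.28 TPM (log2 fold change 1.97).

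Of 23 endoderm genes, 22 were lower in Pcgf2 KO EB day 8 (adjusted p = 9.2e-14, and 0.053 with an estimated correlation), as were 10 of 12 fibroblast genes (adjusted p = 3.9e-08, and 0.053) and 9 of 12 blood and endothelium genes (adjusted p = 2.3e-05, and 0.11). Primed epiblast genes had 13 of 14 up, naive genes 14 of 19 and p53 targets 14 of 15 (adjusted p = 1.4e-08, 6e-09 and 6.2e-08; 0.13, 0.1 and 0.097 with an estimated correlation). Posterior Hox had 18 of 23 up, and 19 adjusted over the list alone (adjusted p = 7.3e-07, and 0.11 with an estimated correlation). Genes of the mitochondrial genome had 9 of 13 down and ribosomal protein genes 10 of 24 up (adjusted p = 0.00072 and 0.0063; 0.51 and 0.68 with an estimated correlation), and the ribosomal call ended with median-of-ratios scaling (adjusted p = 0.09). The other counts were the same when adjusted over the list alone. Limma called 6767 genes, 3692 up and 3075 down, of which 756 rose and 597 fell at least 2-fold. The excess of rises turned with median-of-ratios scaling (3168 up and 3863 down).

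In NPC, the comparison of Pcgf2 KO with WT asked whether Pcgf2 was needed for the neural program. Pou5f1 stood at 329 ± 16 against 1.14 ± 0.48 TPM (log2 fold change 7.29, adjusted p = 1.1e-11). Nanog was at 213 ± 11 against 2.02 ± 0.12 TPM (log2 fold change 6.15) and Zfp42 at 224 ± 20 against 1.03 ± 0.3 TPM (log2 fold change 6.80). Neural genes were low, with Pax6 at 1.23 ± 0.3 against 63.2 ± 15 TPM (log2 fold change -4.83). Hes5 was at 0.396 ± 0.041 against 73.6 ± 26 TPM (log2 fold change -5.69) and Dcx, a microtubule gene of young neurons, was at 0.128 ± 0.077 against 25 ± 2.9 TPM (log2 fold change -4.52). Hoxc5 was at 1.64 ± 0.0043 against 138 ± 8.9 TPM (log2 fold change -5.71) and Hoxb8 at 6.25 ± 1.8 against 193 ± 44 TPM (log2 fold change -4.74). Retinoic acid targets went both ways, since Nr2f1 fell from 222 ± 21 to 1.88 ± 0.63 TPM (log2 fold change -6.29) and Stra8, a retinoic acid target of germ cells, rose from 10.6 ± 5.4 to 465 ± 31 TPM (log2 fold change 5.41). Trophoblast and germline factors appeared, Tfap2c at 190 ± 3.7 against 1.74 ± 0.71 TPM (log2 fold change 6.15). The keratin gene Krt7 was at 282 ± 75 against 8.89 ± 4.1 TPM (log2 fold change 4.87) and Dazl was at 49.8 ± 11 against 0.206 ± 0.06 TPM (log2 fold change 5.38). Gata2 rose to 502 ± 28 from 29.5 ± 4.3 TPM (log2 fold change 4.05). Cbx7, the main Cbx subunit of stem cell PRC1, was at 241 ± 10 against 4.14 ± 0.31 TPM (log2 fold change 5.56). Epop, a partner of PRC2 in stem cells, was at 268 ± 5.8 against 18.9 ± 3.9 TPM (log2 fold change 3.77).

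All 19 naive genes were higher in Pcgf2 KO NPC (adjusted p = 7.3e-12, and 0.066 with an estimated correlation). Of neural progenitor genes 23 of 27 were lower, of neuron genes 23 of 26 and of anterior Hox genes 14 of 15 (adjusted p = 6.3e-08, 2e-08 and 2.1e-07; 0.21, 0.19 and 0.053 with an estimated correlation). Posterior Hox genes split, 10 up and 10 down of 23, with a median of 0.24 while the list test pointed down (adjusted p = 0.52). Trophectoderm had 10 of 11 up, germline 15 of 17 and 2-cell-like 11 of 11 (adjusted p = 2.9e-06, 9.8e-06 and 4.8e-07; 0.053, 0.084 and 0.15 with an estimated correlation). Polycomb-target factors had 10 of 50 up and 34 down, and retinoic acid response genes 5 of 19 up and 14 down (adjusted p = 0.00047 and 0.0073; 0.17 and 0.094 with an estimated correlation). PRC2 subunit genes had 9 of 12 up and 2 down (adjusted p = 0.022, and 0.49 with an estimated correlation), blood and endothelium genes 10 of 12 down (adjusted p = 0.0011, and 0.17) and fibroblast genes 8 of 12 down (adjusted p = 0.011, and 0.17). Every count so far in this paragraph was the same when adjusted over the list alone. Lists that did not pass included primitive streak and mesoderm (6 of 23 up, 10 down; adjusted p = 0.33), cardiac and muscle (5 of 12 up, 2 down; adjusted p = 0.82), forebrain (1 of 6 up, 2 down; adjusted p = 0.37) and Cdk inhibitors (2 of 7 up, 3 down; adjusted p = 0.96), also with the same counts. Called genes numbered 11875, 5659 up and 6216 down, and 5321 moved at least 2-fold, 2653 up and 2668 down.

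**Figure D2:**
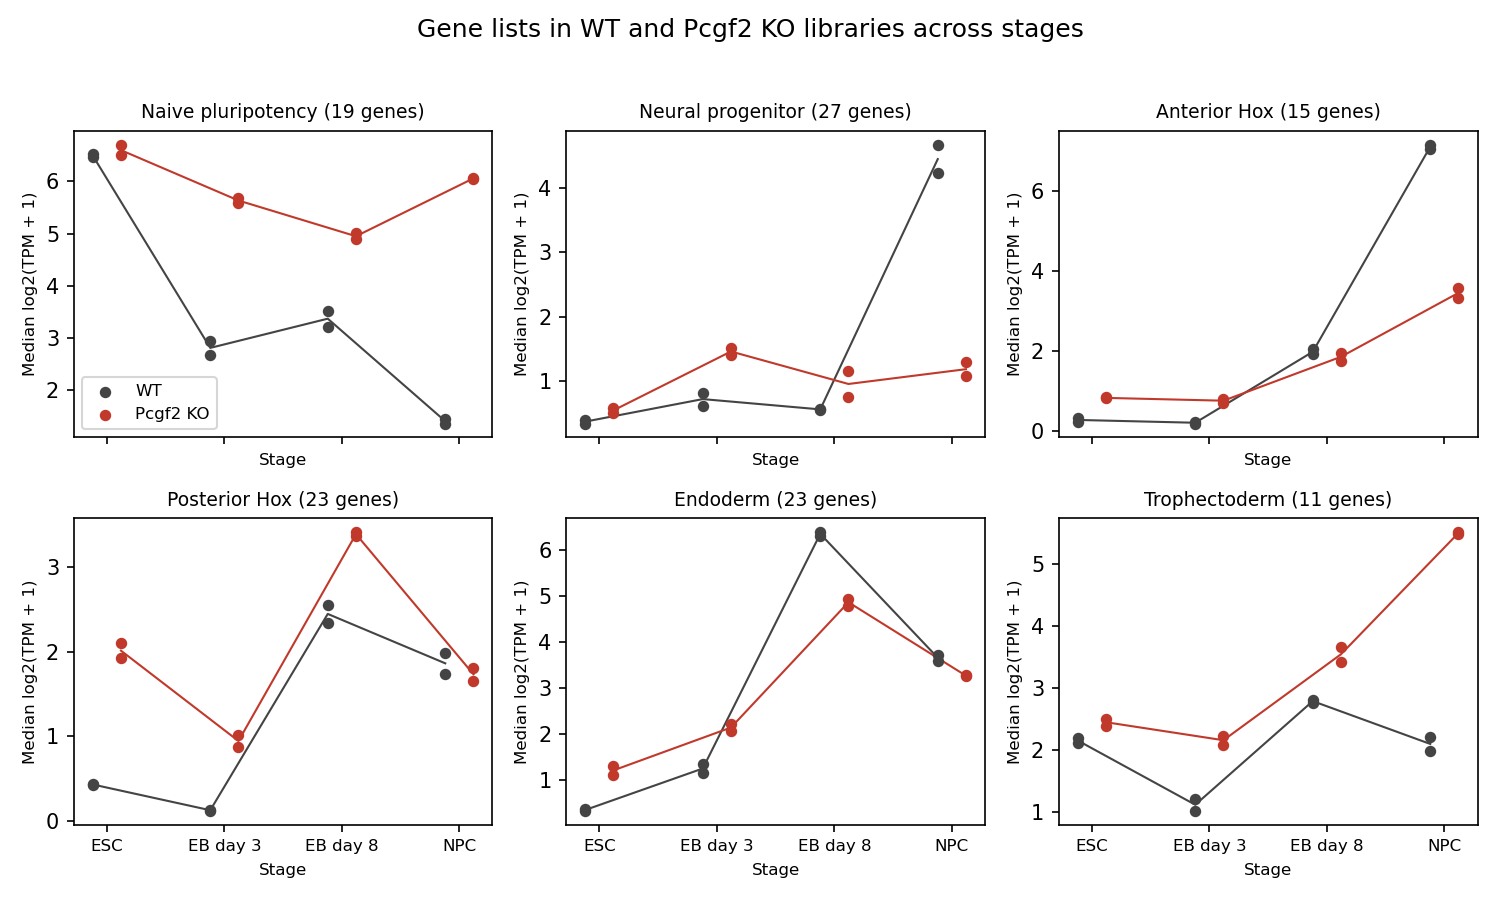
Median log2(TPM + 1) over the tested members of 6 gene lists in the first table, with a point per library (WT black, Pcgf2 KO red) and lines through the group means. The lists were written before the data were examined.

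Genes that WT cells switched on between ESC and NPC were followed in the knock-outs, with genes picked by 1 WT NPC library and compared in the other. Among the 2284 and 2130 genes at least 4-fold higher in the picking library, the median log2 difference of Pcgf2 KO from WT NPC was -1.34 and -1.51, and 60.9% and 65.3% of them were at least 2-fold lower. With a 2-fold limit the mean of the 2 medians was -0.72 instead of -1.43. The 665 and 643 genes that WT cells had lowered at least 4-fold were higher in Pcgf2 KO NPC, with medians of 1.77 and 1.86, and the mean of the medians was 0.89 with the 2-fold limit instead of 1.82. In the second table the medians of induced genes were -0.99 and -1.11 for Phc1 KO and -1.07 and -1.22 for Phc1-SAM KO (1010 and 963 genes comparable between tables), and with the 2-fold limit the means of the medians were -0.65 instead of -1.05 and -0.70 instead of -1.14. These are differences across genes, which are not independent replicates.

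The Irx3 locus on chromosome 8 holds Fto, Irx3, Irx5 and Irx6, of which Irx3 and Irx5 are Polycomb-bound genes that open during neural differentiation. In WT cells Irx3 (91798511 to 91801654) rose from 0.123 ± 0.0052 TPM in ESC to 45.7 ± 12 TPM in NPC (log2 fold change 5.36, adjusted p = 1.1e-10) and Irx5 (92357796 to 92361456) from 0.142 ± 0.072 to 22.3 ± 4.6 TPM (log2 fold change 4.34). Before differentiation Irx5 was at 0.562 ± 0.05 TPM in Pcgf2 KO ESC (log2 fold change 0.45, adjusted p = 0.04), a call that ended with any of the 4 libraries left out (adjusted p = 0.082 to 0.17), without the filter on low values (adjusted p = 0.072), with quantile normalization (adjusted p = 0.15) and without the EB day 8 libraries (adjusted p = 0.053). On EB day 3 both genes were higher in Pcgf2 KO, Irx3 at 2.78 ± 0.0071 against 1.16 ± 0.019 TPM (log2 fold change 0.81, adjusted p = 0.0015) and Irx5 at 2.23 ± 0.16 against 0.458 ± 0.2 TPM (log2 fold change 1.15, adjusted p = 9.7e-05). On EB day 8 no difference was detectable, with Irx3 at 14.3 ± 0.64 and 14.5 ± 2.5 TPM and Irx5 at 3.66 ± 0.25 and 3.61 ± 0.52 TPM. In NPC Irx5 fell to 1.55 ± 0.073 TPM in Pcgf2 KO (log2 fold change -3.18, adjusted p = 7.1e-09), whereas Irx3 kept 30 ± 3.1 TPM (log2 fold change -0.58, adjusted p = 0.0077). The Irx3 call ended without WT replicate 2 (log2 fold change -0.32, adjusted p = 0.095) or knock-out replicate 1 (log2 fold change -0.47, adjusted p = 0.062). Mmp2, a neighbouring protease gene, dropped from 125 ± 23 to 10.3 ± 1.1 TPM (log2 fold change -3.48) and Fto from 68 ± 1.8 to 47.8 ± 3.5 TPM (log2 fold change -0.50, adjusted p = 4.1e-05). Irx6 stood at 0.733 ± 0.21 TPM in WT NPC and 0.0244 ± 0.0018 TPM in Pcgf2 KO NPC, under the limit of 1 TPM for testing. As a list, 4 of 6 tested genes of the locus were lower in Pcgf2 KO NPC (adjusted p = 0.099), also when adjusted over the list alone.

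The effect of Pcgf2 KO differed between stages when the difference itself was tested. Between NPC and ESC the effect changed for 10269 genes, upward for 4132 and downward for 6137. Pou5f1 (difference in log2 fold change 7.57, adjusted p = 4.5e-10), Nanog (5.78) and Lefty1 (9.39) moved up relative to their ESC effect. Hes5 (-5.75), Hoxc5 (-7.22), Hoxc6 (-6.32), Irx5 (-3.63) and Irx3 (-0.93) moved down. Among them Hes5, Irx5 and Irx3 lay near the floor in both ESC groups and could hardly fall there. Anterior Hox genes had 15 of 15 down and naive genes 18 of 19 up, also when adjusted over the list alone (adjusted p = 2.4e-08 and 6.2e-14; 0.053 for both with an estimated correlation). With median-of-ratios scaling 5170 went up and 4831 down. Between NPC and EB day 8 the effect changed for 9963 genes, 4480 up and 5483 down, a majority that turned with median-of-ratios scaling (4988 up and 4602 down). Retinoic acid was the difference in culture that the labels name, but the WT cells of these stages also differed in Y-linked transcripts. Eif2s3y in WT was at 0.811 of its Pcgf2 KO level on EB day 8 and at 0.03 in NPC. The ligand and the WT cells cannot be told apart here. Pou5f1 (5.57) and Nanog (4.18) moved up. Afp (3.45) and Postn (4.54) did too, having fallen on EB day 8, and lay near the floor in NPC, at 0.642 ± 0.27 and 0.547 ± 0.15 TPM in Pcgf2 KO. Hes5 (-5.84), Hoxb8 (-5.55) and Irx5 (-3.20) moved down, of which Hes5 lay near the floor in both EB day 8 groups. Neural progenitor genes had 22 of 27 down and 23 adjusted over the list alone (adjusted p = 1.1e-09, and 0.16 with an estimated correlation).

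Phc1 KO and Phc1-SAM KO ESC were each compared with WT ESC to learn whether losing Phc1, or its SAM domain alone, released the same genes. Because the WT columns of the second table appeared to hold another unit, these tests used 8689 genes whose WT values could be matched between tables. In ESC labelled Phc1-SAM KO, Hoxd13 rose from 0.684 ± 0.12 to 8.65 ± 0.73 TPM (log2 fold change 2.52, adjusted p = 9.1e-06) and Hoxa9 from 0.168 ± 0.052 to 6.37 ± 1.6 TPM (log2 fold change 2.64). Plk2, a p53 target, rose from 10.2 ± 0.98 to 47.4 ± 0.47 TPM (log2 fold change 2.11), and Lefty1 fell from 131 ± 8.2 to 14 ± 3.4 TPM (log2 fold change -3.16). In ESC labelled Phc1 KO, Hoxd13 reached 4.6 ± 0.11 TPM (log2 fold change 1.73). Plk2 reached 76.5 ± 3.4 TPM (log2 fold change 2.79) and Irx5 4.9 ± 0.48 against 0.142 ± 0.09 TPM (log2 fold change 2.37), and Lefty1 fell to 8.29 ± 3 TPM (log2 fold change -3.87). Of 6 tested Irx3 locus genes, 3 rose in Phc1-SAM KO ESC, 0 of them at least 2-fold, against 4 and 2 in Phc1 KO ESC. Phc1 was lower than in WT by a log2 fold change of -0.49 (adjusted p = 0.024), and this call ended without WT replicate 1 (adjusted p = 0.13) or either knock-out replicate (adjusted p = 0.088 and 0.083) and turned direction with the WT columns as deposited (log2 fold change 0.14). The same Phc1 KO libraries carried abundant transcripts of fibroblasts, with the calcium-binding protein gene S100a4 at 339 ± 14 against 0.144 ± 0.2 TPM (log2 fold change 8.23, adjusted p = 2.5e-08). The collagen gene Col1a1 was at 222 ± 9.2 against 0.639 ± 0.41 TPM (log2 fold change 7.11). Phc1-SAM KO had less of both, with S100a4 at 10.8 ± 0.32 TPM (log2 fold change 3.38) and Col1a1 at 8.4 ± 0.11 TPM (log2 fold change 2.54). Whether the Irx5 rise in Phc1 KO ESC came with these fibroblast transcripts was not tested.

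Posterior Hox genes had 14 of 18 up in Phc1 KO ESC and 13 of 18 in Phc1-SAM KO ESC (adjusted p = 0.046 and 0.00012; 0.17 and 0.053 with an estimated correlation), and the call in Phc1 KO ended with a limit of 5 TPM (adjusted p = 0.12). The p53 list had 9 of 10 up in each (adjusted p = 0.00036 and 6.3e-07; 0.11 and 0.053 with an estimated correlation), and all 8 fibroblast genes tested rose in each (adjusted p = 1.7e-05 and 0.00055; 0.21 and 0.31 with an estimated correlation). Polycomb-target factors had 19 of 45 up and none down in Phc1-SAM KO (adjusted p = 0.026, and 0.42 with an estimated correlation; 0.052 with a limit of 5 TPM), among them Nkx2-9, a neural tube factor, at 13.1 ± 0.54 against 1.14 ± 0.4 TPM. Adjusted over the list alone, these counts were the same. In Phc1 KO 4708 genes were called, 3982 up and 726 down, with a median shift of 0.38, and in Phc1-SAM KO 3241, 2575 up and 666 down, with a median shift of 0.20. The excess of rises depended on the scaling. Median-of-ratios scaling gave 2329 up and 2259 down for Phc1 KO and 1580 up and 1738 down for Phc1-SAM KO. Quantile normalization gave 1818 up and 2631 down and 1343 up and 1529 down. The limit to genes with matched WT values also let in genes near 0 in WT, which can rise but hardly fall. How far this added to the rises was not tested. With the WT columns as deposited, and no limit to matched genes, the counts were 13397 and 12442. With agreement between the tables required within 1.2-fold, and thus fewer genes, the count for Phc1-SAM KO was 2097. These counts differ from the main ones in the genes tested too.

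Phc1 KO and Phc1-SAM KO NPC were set against WT NPC with the same question as for Pcgf2. Pou5f1 stood at 418 ± 5.9 TPM in Phc1 KO and 386 ± 6.4 TPM in Phc1-SAM KO against 1.15 ± 0.39 TPM in WT (log2 fold change 7.62 and 7.50, adjusted p = 4.9e-09 and 4.6e-09). Zfp42 was at 185 ± 3.4 and 141 ± 2.1 TPM against 0.828 ± 0.42 TPM. Neurog1 fell to 1.53 ± 0.71 and 1.62 ± 0.33 TPM from 65 ± 23 TPM (log2 fold change -4.69 and -4.61). Gap43, a growth cone gene of neurons, fell to 1.51 ± 0.19 and 1.68 ± 0.014 TPM from 82.6 ± 24 TPM (log2 fold change -5.03 and -4.93). Irx3 fell to 7.41 ± 0.35 and 8.41 ± 1.3 TPM from 56.2 ± 10 TPM (log2 fold change -2.75 and -2.60, adjusted p = 1.9e-06 and 2.4e-06). Irx5 fell to 1.38 ± 0.18 and 1.71 ± 0.027 TPM from 25.1 ± 6.4 TPM (log2 fold change -3.43 and -3.25). Fto was at 59.8 ± 2.8 and 56.8 ± 1.1 TPM against 78.4 ± 2 TPM (log2 fold change -0.39 and -0.46), a direction that turned when the WT columns were used as deposited (log2 fold change 0.63 and 0.56). Hoxc9, a thoracic Hox gene, rose to 18.4 ± 0.074 and 14 ± 0.53 TPM from 1.76 ± 0.6 TPM (log2 fold change 2.83 and 2.45). Of 12 retinoic acid response genes tested, 9 fell in each knock-out and 2, Stra8 and Cdx1, rose, Cdx1 to 67.5 ± 2.6 and 74 ± 1.5 TPM from 0.178 ± 0.0018 TPM. The embryonic globin Hbb-y, at 313 ± 33 TPM in WT, was at 0.0607 ± 0.086 and 0.266 ± 0.13 TPM.

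In each of these NPC knock-outs 13 of 15 naive genes rose, and 14 adjusted over the list alone (adjusted p = 1.6e-09 and 5.4e-09; 0.053 for each with an estimated correlation). Of neuron genes 17 of 18 fell (adjusted p = 1.5e-08 and 2.3e-08; 0.2 for each with an estimated correlation) and of neural progenitor genes 15 of 18 (adjusted p = 1.7e-06 and 3.1e-06; 0.16 and 0.17 with an estimated correlation). All 9 tested 2-cell-like genes and 11 of 12 germline genes rose in each (adjusted p = 5.1e-06 and 9.8e-06, then 1.3e-05 and 9.8e-06; 0.053 for every one with an estimated correlation). The retinoic acid response list did not pass (adjusted p = 0.063 and 0.079), and 10 of its genes fell in Phc1-SAM KO adjusted over the list alone. Posterior Hox had 9 of 13 up and 1 down in each (adjusted p = 0.0033 and 0.0019; 0.1 and 0.094 with an estimated correlation). Only 13 of its 24 members were tested, so this count does not stand for the whole list. With 23 tested, Pcgf2 KO NPC had 10 up and 10 down. The Irx3 locus had 5 of 6 genes down in each (adjusted p = 0.011 and 0.012; 0.13 for each with an estimated correlation), and all 6 in Phc1 KO adjusted over the list alone. Anterior Hox genes could not be judged, as only 2 had comparable WT values. Of 8077 genes, 4701 were called in Phc1 KO (2160 up, 2541 down) and 4909 in Phc1-SAM KO (2196 up, 2713 down). With the WT columns as deposited, which tested more genes, 13317 and 13195 were called. Counts without a separate value were the same when adjusted over the list alone.

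Phc1 KO and Phc1-SAM KO, both in the second table with values of one unit, were then compared directly to separate the domain from the whole protein. In ESC the genes that rose most in Phc1 KO included fibroblast genes, S100a4 (log2 fold change 4.85, adjusted p = 4.4e-07), Col1a1 (4.57) and the proteoglycan gene Bgn, at 240 ± 14 against 9.08 ± 0.33 TPM (4.58). Pou5f1 was lower in Phc1 KO, at 1140 ± 17 against 1800 ± 12 TPM (log2 fold change -0.66), and Nanog at 355 ± 1.6 against 532 ± 7.3 TPM (log2 fold change -0.58). Hoxa9 was lower as well, at 2.34 ± 0.09 against 6.37 ± 1.6 TPM (log2 fold change -1.12). All 11 fibroblast genes tested were higher, 15 of 19 naive genes were lower and 21 of 24 ribosomal protein genes were lower, also when adjusted over the list alone (adjusted p = 2.5e-08, 7.1e-08 and 2.2e-12; 0.094, 0.053 and 0.11 with an estimated correlation). TPM are shares of a library, so fibroblast RNA in the Phc1 KO libraries would by itself lower the share of stem cell transcripts. Of naive genes 0 of 19 fell at least 2-fold (median -0.35), and such dilution cannot be told apart from an effect of the genotype. The ribosomal call ended with quantile normalization (adjusted p = 0.051). Genes of the mitochondrial genome had 12 of 13 up, and 13 adjusted over the list alone (adjusted p = 0.00038, and 0.52 with an estimated correlation). Neural crest genes had 7 of 10 up and 1 down, 8 up adjusted over the list alone (adjusted p = 0.016, and 0.17 with an estimated correlation). Limma called 6904 of 15775 genes, 4877 up and 2027 down, with a median shift of 0.13. Median-of-ratios scaling gave 3231 up and 4226 down, and quantile normalization 2821 up and 3994 down.

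**Figure D3:**
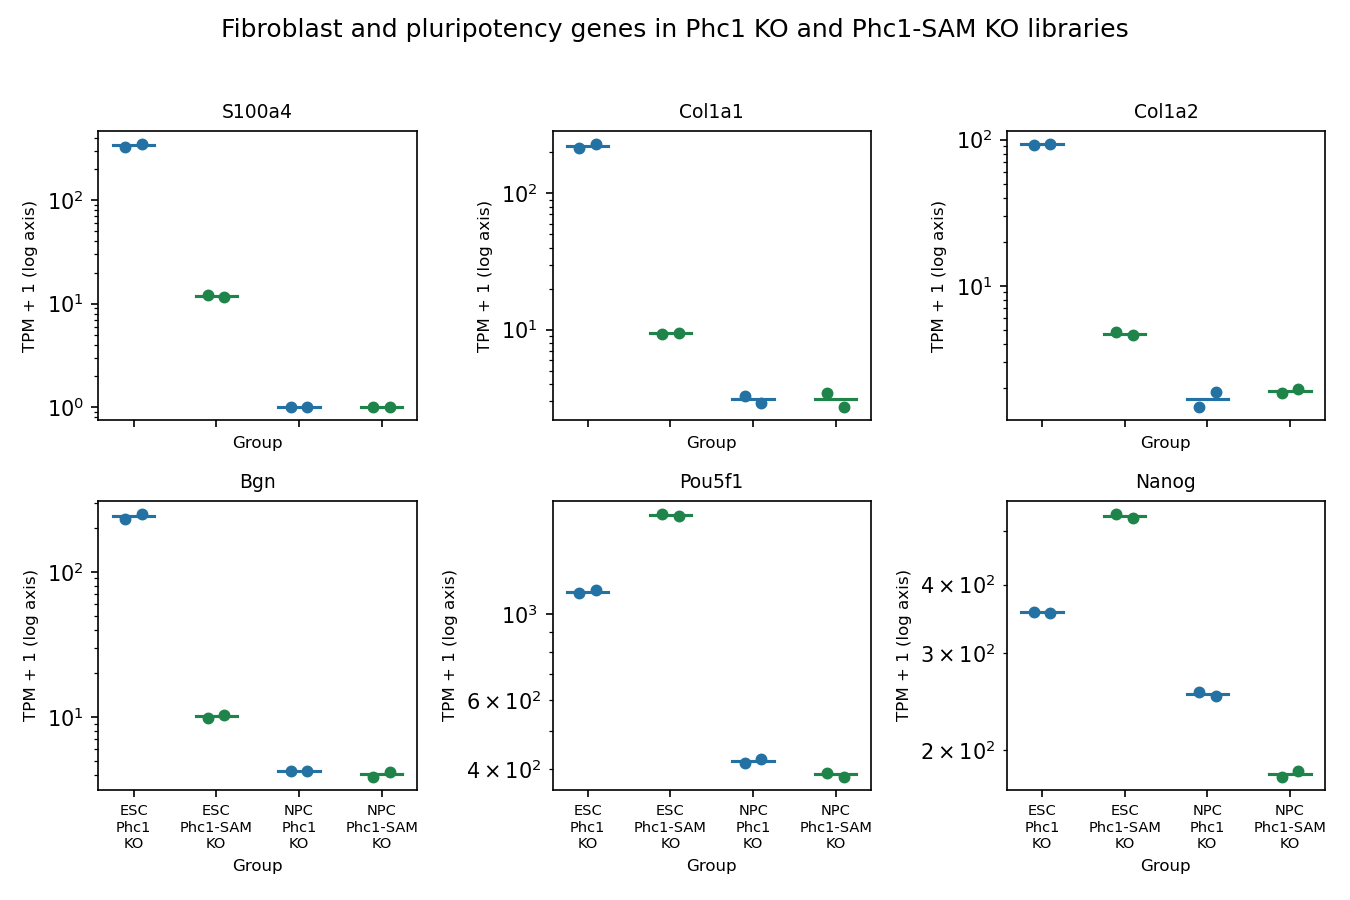
TPM + 1 of 4 fibroblast genes and 2 pluripotency genes on a log axis in the knock-out libraries of the second table, with a point per library and a line at the mean of each group. The fibroblast genes are highest in the ESC libraries labelled Phc1 KO.

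In NPC, Phc1 KO and Phc1-SAM KO were close to each other. Endoderm genes were lower in Phc1 KO, with the apolipoprotein gene Apoa1 at 0.553 ± 0.14 against 10 ± 1.4 TPM (log2 fold change -2.82, adjusted p = 0.0014). Cubn, an uptake receptor of visceral endoderm, was at 4.78 ± 0.21 against 18.9 ± 0.13 TPM (log2 fold change -1.79, adjusted p = 0.0014). Grb10 was lower too, at 4.76 ± 0.11 against 45.1 ± 0.79 TPM (adjusted p = 0.00014). Nanog was higher, at 252 ± 3.2 against 180 ± 2.7 TPM (log2 fold change 0.48), as was Sox2, at 91.7 ± 1 against 56.3 ± 1.2 TPM (log2 fold change 0.69), and both calls ended with the WT columns as deposited in the fit (adjusted p = 0.097 and 0.063). Irx3 (log2 fold change -0.15, adjusted p = 0.58) and Irx5 (log2 fold change -0.19, adjusted p = 0.52) did not pass the test. Of 23 endoderm genes 17 were lower, 18 adjusted over the list alone (adjusted p = 3.1e-20, and 0.053 with an estimated correlation). Naive genes had 8 of 19 up and none down, against 14 up and 2 down adjusted over the list alone (adjusted p = 3.2e-08, and 0.053 with an estimated correlation). Called genes numbered 637, 397 up and 240 down, or 253 up and 315 down with median-of-ratios scaling and 286 up and 310 down with quantile normalization. That count fell to 68 and 65 without Phc1 KO replicate 1 or 2 and to 150 and 149 without Phc1-SAM KO replicate 1 or 2. With only the groups compared it was 364, and with the WT columns as deposited 256.

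The calls of the 3 knock-outs were compared with each other at each stage, to see whether they moved the same genes. In NPC, Pcgf2 KO and Phc1 KO shared 3496 calls of one direction, 1666 up where independent lists would share 787 and 1830 down where they would share 920, while 312 calls were opposite and 1444 were shared at a 2-fold limit. Phc1 KO and Phc1-SAM KO shared 4327 with 7 opposite, and 1625 at that limit. In ESC the pair Pcgf2 KO and Phc1 KO shared 1880 calls, 1561 up against 1113 for independent lists and 319 down against 81, with 255 opposite and 270 shared at the 2-fold limit, and Pcgf2 KO and Phc1-SAM KO shared 1527 with 188 opposite and 213 at that limit. Each pair used the same WT libraries as controls, which by itself makes fold changes alike. In 20 simulated draws without any effect, pairs shared at most 1 call. That count is low by construction, because such draws hold hardly any calls, so it cannot gauge the overlap. The draws held only the spread between libraries, not a lasting difference between WT and knock-out cells such as that in Y-linked transcripts. Within that limit, the simulated covariance of fold changes was 0.012 in NPC against 1.4 observed for Pcgf2 KO and Phc1 KO, and 0.013 in ESC against 0.173 observed. The correlation of fold changes across genes, which are not independent replicates, was 0.35 for that pair in ESC against 0.26 simulated, and 0.83 in NPC against 0.28. The controls were not divided between the comparisons, which would have left 1 WT library for each. Part of the excess may thus come from the shared controls, including a lasting difference of the WT cells.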

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

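The test of retinoic acid response genes and that of the second fibroblast list were written before their results were seen, and the other tests in this part were chosen after the results were seen.

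A test of the difference between stages flagged the effect of Pcgf2 KO on 10269 genes between NPC and ESC and on 9963 genes between NPC and EB day 8. Relative to ESC, the log2 effect in NPC was higher by 7.57 for Pou5f1, 5.78 for Nanog and 9.39 for Lefty1, and it changed by -5.75 for Hes5, -7.22 for Hoxc5, -6.32 for Hoxc6, -3.63 for Irx5 and -0.93 for Irx3. Relative to EB day 8, it was higher by 5.57 for Pou5f1, 4.18 for Nanog, 3.45 for Afp and 4.54 for Postn, and it changed by -5.84 for Hes5, -5.55 for Hoxb8 and -3.20 for Irx5. For Afp and Postn the difference reflects their falls on EB day 8 (-3.11 and -5.94), where their effect in NPC was smaller. Hes5 lay near the floor in ESC (0.105 ± 0.15 TPM in Pcgf2 KO, 0.0589 ± 0.03 in WT) and on EB day 8 (0.259 ± 0.3 and 0.133 ± 0.19 TPM). Irx5 (0.562 ± 0.05 and 0.142 ± 0.072 TPM) and Irx3 (0.437 ± 0.015 and 0.123 ± 0.0052 TPM) did so in ESC. They could hardly fall there, so these differences reflect mainly the NPC effect. For the other differences an effect of Pcgf2 that depends on stage stays open as a biological explanation, untested here. The reason is that 1 set of libraries cannot show that the genotype, and not the course of these cultures, made the difference. The contrast with EB day 8 also sets WT groups that differ in Y-linked transcripts against each other.

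Pluripotency transcripts were abundant in Pcgf2 KO NPC, where Pou5f1 stood at 329 ± 16 TPM (SD, n = 2). A mixture of stem cells as in the Pcgf2 KO ESC libraries with progenitors as in WT NPC was argued against: naive genes put the stem cell share at 0.408, with single genes from 0.167 to 5.37, while the median neural progenitor gene kept 0.0351 of its WT level and 20 of 21 such genes lay below 0.296. Absence of any response to retinoic acid was argued against as well, because 14 of 19 response genes were higher in Pcgf2 KO NPC than in Pcgf2 KO EB day 8, although naive pluripotency (14 of 19, and 15 adjusted over the list alone), trophectoderm (10 of 11) and 2-cell-like genes (11 of 11) were higher there too, so the rise was not limited to that list. Stem cells with other transcript levels, or cells of a further type, stay open. The data are thus consistent with cells that sensed retinoic acid without taking the WT neural path, a hypothesis found and tested on the same libraries.

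Fibroblast transcripts were abundant in the ESC libraries labelled Phc1 KO, with S100a4 at 339 ± 14 TPM (SD, n = 2). Of a second list of fibroblast genes, written after the pattern was seen, 15 of 18 tested were called at least 2-fold higher than in Phc1-SAM KO ESC, in line with RNA from fibroblasts in those libraries. An effect of Phc1 loss beyond that of its SAM domain, holding at both stages, was argued against. Among NPC, 0 of 11 fibroblast genes were at least 2-fold higher in Phc1 KO than in Phc1-SAM KO. An effect common to both knock-outs cancels in that contrast, which thus cannot address it. Against WT ESC, all 8 fibroblast genes tested rose in Phc1-SAM KO too, with a median of 1.38 against 4.81 in Phc1 KO. For stem cells passing through primitive streak and early mesoderm, 6 of 19 genes were at least 2-fold higher in Phc1 KO than in Phc1-SAM KO ESC, which decides nothing. Whether fibroblasts came with the culture or arose in it cannot be told from RNA alone, and an effect of Phc1 loss limited to ESC stays open.

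For 4 Y-linked genes, chosen after their values were seen (Uba1y, Eif2s3y, Uty and Ddx3y, at 5 TPM or more in Pcgf2 KO ESC), WT levels were low in ESC, EB day 3 and NPC: the highest ratio of WT to Pcgf2 KO in those stages was 0.0807, which is in line with a Y chromosome absent from most WT cells of those stages. Kdm5d, another Y-linked gene, lay below that limit, and its difference in ESC did not pass (log2 fold change 0.28, adjusted p = 0.16), which this explanation leaves unaccounted for. At EB day 8 the median ratio over 3 of these genes was 0.75, which argues against a rise of Y-linked genes after loss of a PRC1 subunit, although Uba1y was at 0.03 there too. Exchanged labels at EB day 8 were argued against, since the lowest Eif2s3y level in the libraries labelled Pcgf2 KO was 1.17 of the Pcgf2 KO ESC mean. WT EB day 8 may thus come from other WT cells than the remaining stages. This limits comparisons between WT stages that involve it, and the difference of the Pcgf2 KO effect between NPC and EB day 8. Knock-out against WT in ESC, EB day 3 and NPC sets cells with these transcripts against cells with few.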

How the results depend on the processing

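The WT columns as deposited, agreement within 1.2-fold, the 2-fold limit on comparisons with WT in ESC, and the fits without the EB day 8 or ESC Phc1 KO libraries were chosen after seeing the data. Under alternatives 205 counts stayed within 1.5 times and 26 did not. Of values for genes followed under the naming rule, 3597 kept direction and call, 22 lost and 2 gained the call and 9 turned. Of list calls, 887 held, 217 ended and 2 turned. With only the groups compared, Pcgf2 KO in ESC gave 4098 genes and Phc1 KO against Phc1-SAM KO in NPC 364, the latter also 302 with the replicate block, 256 with WT columns as deposited and 65 to 150 leaving out each library, where the lone library is assumed to vary like the other groups. WT columns as deposited gave 13397 and 13317 (Phc1 KO, ESC and NPC) and 12442 and 13195 (Phc1-SAM KO), where more genes were tested and their unit appeared to differ. Agreement within 1.2-fold, which tested fewer genes, gave 2097 for Phc1-SAM KO ESC. A 2-fold limit gave 1768 and 596 for Phc1 KO and Phc1-SAM KO ESC. Estimated correlation kept 0 list calls and fry made 332. Genes induced in WT NPC had a Pcgf2 KO median of -0.72 at 2-fold, -1.23 with pseudocount 0.1 and -1.72 with median-of-ratios scaling. Overlaps at 2-fold were 270, 213 and 441 in ESC and 1444, 1518 and 1625 in NPC (Pcgf2 with Phc1, Pcgf2 with Phc1-SAM, Phc1 with Phc1-SAM). On EB day 8 under Pcgf2 KO, Irx5 turned with median-of-ratios scaling (-0.04) and quantile normalization (-0.06), and leaving out each library gave -0.10 to 0.13 for Irx5 and -0.18 to 0.15 for Irx3. With WT columns as deposited Phc1 in Phc1 KO ESC turned to 0.14 and Fto in NPC to 0.63 and 0.56. Ribosomal proteins between WT NPC and EB day 8 turned with quantile normalization (adjusted p = 0.99) and neuron genes in Phc1 KO ESC with fry (0.56). Where not stated, the cause was not tested. Replicate numbers showed no steady pairing (correlations of -0.32 to 0.23 over 28 pairs of groups, and -0.061 to 0.055 over 6). Pcgf2 KO against Phc1 KO was not run, as the tables differ. Depth is unknown, so what it limits cannot be given.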

Other observations

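Among Y-linked genes, chosen after their values were seen, 3 differed between Phc1 KO and Phc1-SAM KO ESC. Ddx3y was higher in Phc1 KO by a log2 fold change of 0.83 (adjusted p = 0.0012), Eif2s3y by 1.88 (adjusted p = 0.0021) and Uty by 1.31 (adjusted p = 0.00018), while Kdm5d did not pass (0.03, adjusted p = 0.89). In NPC of the same labels none of these 4 passed limma's test, with Ddx3y at -0.01, Eif2s3y at -0.19 (adjusted p = 0.77), Uty at 0.17 (adjusted p = 0.46) and Kdm5d at 0.12 (adjusted p = 0.70). Levels also differed between the stages of one label: Eif2s3y stood at 3.59 ± 2.2 TPM in ESC and 35.7 ± 1.4 TPM in NPC labelled Phc1-SAM KO, and at 14.9 ± 1.3 and 31.2 ± 0.79 TPM in those labelled Phc1 KO (SD, n = 2). The ESC libraries labelled Phc1 KO were also those with abundant fibroblast transcripts. Whether the Y-linked difference in ESC came with that RNA was not tested.

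Bmi1, a paralog of Pcgf2, stood at 15.1 ± 0.6 TPM in Pcgf2 KO and 9.79 ± 2.1 TPM in WT ESC (SD, n = 2), 14.9 ± 0.62 and 7.82 ± 1.7 TPM on EB day 3, 14.1 ± 0.029 and 12 ± 1.7 TPM on EB day 8, and 43.9 ± 1.7 and 46.5 ± 4.2 TPM in NPC. In the second table it stood at 28.8 ± 1.1 TPM in Phc1 KO and 15.9 ± 1.7 TPM in Phc1-SAM KO ESC, and at 47.1 ± 6.7 and 48 ± 2 TPM in their NPC.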
